A study of Mus musculus with 13 samples.

How the data were processed

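RNA sequencing was measured in 13 mouse brain libraries: 3 control and 4 knockout libraries of isolated brain microvascular endothelial cells, and 3 control and 3 knockout libraries of ribosome-bound RNA from tagged astrocytes, all at postnatal day 75. Whole-brain samples named in the study's design text were not analysed here. Per the labels, libraries were made with Illumina Stranded mRNA Prep from RNA with an integrity number above 8.0. Per the submitters' processing notes, HISAT2, edgeR and the genome build GRCm39 were used; the counter and the annotation are not given in the sources used here. The deposited table holds, for each library, a raw count per Ensembl gene, in whole numbers and not pooled over replicates. It also holds RPKM, which the authors computed, per the file headers. The RPKM values were checked against the counts: count divided by library total and RPKM gave the same gene length in all libraries for each of 35912 genes. The strand used for counting is not given, so values of genes that overlap others on the opposite strand are uncertain, as are values of near-identical copies such as Serpina1b, Serpina1d and Serpina1e, Hba-a1 and Hba-a2, or Hbb-bs and Hbb-bt.

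Gene symbols were matched by Ensembl ID to a GRCm38 annotation, used for names and gene order only, so no coordinates are given. Of 55416 IDs, 52083 (94%) matched, holding 99.2% of the counts, and 68 IDs that share a symbol were kept under their own ID. Totals were 40617863 to 72236333 counts per library. A count of 0 allows up to 3 counts, or 0.0415 to 0.0739 CPM, and this floor covers counting error only. Replicates differed by far more than counting error, with a chi-square per degree of freedom of at least 17.2 between libraries of a group. Mitochondrial transcripts made up 3.091 to 4.42% of counts in endothelial controls, 2.504 to 3.755% in endothelial knockouts and 0.003316 to 0.007537% in astrocyte libraries.

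Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr with the groups of the fit (minimum count 10, minimum total 15), robust quasi-likelihood fits and F-tests, and Benjamini-Hochberg adjustment at 0.05. The endothelial and astrocyte comparisons, knockout against control, used the 7 and 6 libraries of their fraction. The cell fraction comparison used the 6 control libraries, and the difference between the fractions was the interaction term of 1 fit over all 13. No replicate block was used, since the labels state none. The SE of a log2 change was taken from the F statistic. Overlap of the calls was set against independent lists with Fisher's exact test, two-sided.

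The 36 gene lists (22 of pathways, 14 of cell type markers; 506 genes, all matched) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Members were counted past 0.05 over all genes and adjusted over the list alone. Several members are expressed by more than 1 cell type, and some are in more than 1 list. The comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. That rule takes Pdcd10, Krit1 and Ccm2; the 10 largest increases and decreases among genes past the threshold with an average log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes (165 of 2898 eligible in endothelial cells, 213 of 3326 in astrocyte RNA); up to 4 members per list with a member past the threshold and up to 2 per other list, by smallest p; the 10 interaction genes with the smallest p; and the most abundant markers per cell type. Klf2, Klf4, the sex-linked genes and the values of interaction genes in single fractions lie outside the rule and were chosen after their values were seen. For many lists the text gives values for only some of the members that the rule takes, chosen after their values were seen. The members without a value in the text lost their calls more often when 1 library was left out than the others did, and they are included in every count. Of the genes the rule takes, 4 are not reported here.

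Simulated data held 200 changed genes at folds of 1.5, 2 and 4. In the endothelial design edgeR recovered 13.4, 56.7 and 86.4% (2.8% of calls false). In the astrocyte design it recovered 35.8, 74.6 and 100% (11.4% false), in the cell fraction design 19.4, 70.1 and 93.9% (7.58% false), and for the interaction 7.46, 40.3 and 81.8% (3.37% false). DESeq2 had 21.4 to 33.3% false calls. These rates may not hold for low-count genes, not tested apart. Camera called the 1 shifted list and 0 of 20 unchanged lists in each of the endothelial and astrocyte designs. The simulated lists were random genes drawn independently, whereas members of real lists were correlated (0.989 for microglia markers in endothelial cells). The simulation cannot show how often camera calls unchanged lists of correlated genes.

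Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE factors or library totals in place of TMM, no low-count filter or a stricter one (CPM of 1 in every library of a group), an adjusted p of 0.01, a 2-fold minimum, glmTreat at a fold of 1.5, a replicate block, 1 fit over all 13 libraries, fry, limma-trend on RPKM with pseudocounts of 1 and 0.1 (RPKM of at least 1 in 3 libraries), and leaving out each library in turn. Chosen after seeing the data were a covariate from Y-linked genes, fits without endothelial control 3 and knockout 2, which hold both Xist and Y-linked transcripts, or without astrocyte control 3 and knockout 4, which hold few Y-linked transcripts, and the glucocorticoid and circadian clock lists. Figures were drawn with matplotlib 3.10.9.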

Results

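RNA was sequenced from mice in which the cerebral cavernous malformation gene Pdcd10 (also called CCM3) was deleted in brain endothelial cells. Cerebral cavernous malformations are clusters of dilated, leaky brain capillaries. The recombinase was a tamoxifen-inducible Cre under the Slco1c1 promoter, and control animals carried the floxed Pdcd10 alleles. All animals also carried a ribosome tag under the astrocyte promoter Aldh1l1. Libraries were made from isolated brain microvascular endothelial cells and from RNA bound to the tagged astrocyte ribosomes, at postnatal day 75. There were 3 control and 4 knockout endothelial libraries, and 3 control and 3 knockout astrocyte libraries. The 13 libraries held 40617863 to 72236333 counts each. Endothelial controls held 41741925 to 68606012 counts, endothelial knockouts 45067685 to 55689466, astrocyte controls 40617863 to 64681101 and astrocyte knockouts 58137893 to 72236333. All libraries are labelled as male, but sex-linked transcripts differed between them: Xist, transcribed from the inactive X chromosome, stood at 0.714, 385 and 738 counts-per-million (CPM) of the library total in endothelial controls 2, 3 and 4 and at 708, 411, 0.539 and 754 in endothelial knockouts 1 to 4, and the Y-linked gene Ddx3y at 98.2, 43 and 0 and at 0, 49.3, 97.6 and 0.356. Ddx3y stood at 1.72 CPM in astrocyte control 3 and 2.03 in astrocyte knockout 4, against 40.7 to 55.9 in the other 4 astrocyte libraries. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical. In the text, log2 changes are knockout minus control with their SE, and levels are CPM scaled with TMM factors, as mean ± SD over the libraries of a group. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

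The first comparison concerned the targeted gene. Pdcd10 (ENSMUSG00000027835), a scaffold of the CCM protein complex, was lower in the knockout in both fractions. Per library, endothelial controls 2, 3 and 4 held 20.2, 19.0 and 23.3 CPM of the library total, and endothelial knockouts 1, 2, 3 and 4 held 9.1, 11.9, 9.01 and 9.09. Astrocyte controls 1, 2 and 3 held 22.5, 20.6 and 21.4 CPM, and astrocyte knockouts 2, 3 and 4 held 6.11, 8.71 and 9.36. Pdcd10 fell by 1.05 ± 0.12 (adjusted p = 0.00165) on the log2 scale in endothelial cells and by 1.5 ± 0.16 (adjusted p = 0.00116) in astrocyte RNA, and every knockout library lay below every control library of its fraction. The difference between these 2 changes did not pass the test (0.40 ± 0.21, endothelial minus astrocyte, adjusted p = 0.223). Its complex partners Krit1 and Ccm2 did not pass the test in endothelial cells, with 0.15 ± 0.06 and 0.25 ± 0.10, or in astrocyte RNA, with -0.19 ± 0.09 and 0.05 ± 0.09. Counts per gene do not show which exons the reads covered.

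**Figure D1:**
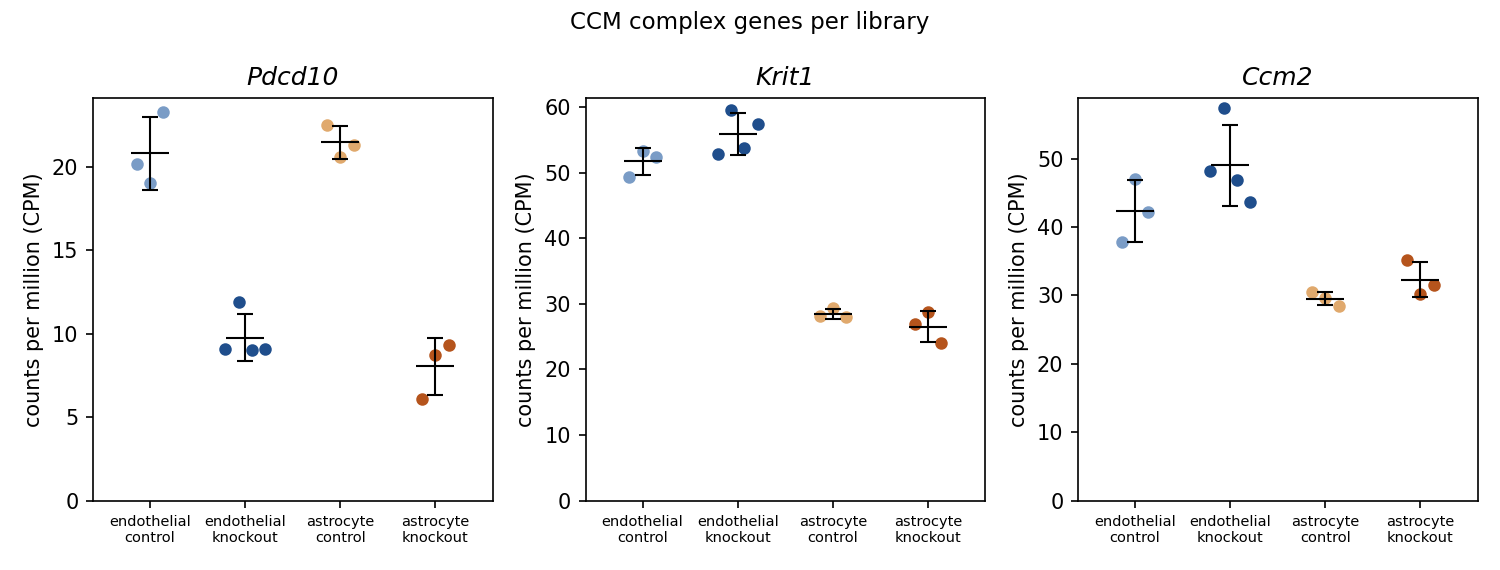
CPM of the library total for Pdcd10, Krit1 and Ccm2 in each library (points), with the mean and SD of each group (black bars). All knockout libraries lie at or below 11.9 CPM of Pdcd10, and all control libraries at or above 19.0, while the control and knockout libraries overlap for Krit1 and Ccm2 in both fractions.

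The control libraries were then compared between fractions, which shows what each preparation held. Endothelial junction and transport genes marked the endothelial fraction: Cldn5, a tight junction protein, stood at 1954 ± 295 CPM against 1.12 ± 0.279 (n = 3 each), Pecam1, an adhesion molecule of endothelial cells, at 1369.8 ± 89 against 1.06 ± 0.383, and Slco1a4, an organic anion transporter, at 2056 ± 114 against 1.14 ± 0.17. Astrocyte RNA was marked by Slc1a2 and Slc1a3, both glutamate transporters, at 12769.7 ± 258 and 4916 ± 324 CPM against 132 ± 80.4 and 53.2 ± 12.7, by Glul, glutamine synthetase, at 18875 ± 1494 against 2088 ± 312, and by Aldh1l1 at 784 ± 41 against 10.01 ± 7.52. All 12 endothelial markers were higher in the endothelial fraction and all 17 astrocyte markers were higher in astrocyte RNA. The log2 difference, endothelial minus astrocyte, was 10.74 ± 0.26 for Cldn5 (adjusted p = 8.3e-08) and -6.53 ± 0.23 for Slc1a3 (adjusted p = 2.76e-07). Of 20285 genes tested, 16284 differed, 8566 higher in endothelial cells and 7718 higher in astrocyte RNA.

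Markers of other cells were present in both preparations. Pericyte, smooth muscle and microglia markers were higher in the endothelial fraction in 9 of 9, 7 of 7 and 12 of 12 genes, among them Rgs5 of pericytes at 1503 ± 82.3 CPM, the smooth muscle actin Acta2 at 588 ± 59.8 and the microglial receptor Csf1r at 264 ± 129.9. So were 8 of 9 perivascular macrophage and monocyte markers, 9 of 9 neutrophil markers, 10 of 12 lymphocyte markers, 8 of 9 oligodendrocyte markers, 7 of 7 ependymal and choroid plexus markers and 6 of 6 tested erythroid markers. The choroid plexus gene Ttr, which encodes transthyretin, stood at 2159.9 ± 384 CPM against 37.6 ± 23.8, and the haemoglobin gene Hbb-bs at 277 ± 44.4 against 1.66 ± 0.279. Neuron markers were higher in astrocyte RNA in 11 of 11 genes, led by the synaptic gene Snap25 at 390.4 ± 88.3 CPM against 6.42 ± 3.71. Fibroblast and oligodendrocyte precursor markers went both ways, with 2 and 3 higher in endothelial cells and 1 and 3 higher in astrocyte RNA, and the fibroblast collagen gene Col1a2 did not pass the test (-0.09 ± 0.23). Endothelial and ribosome-bound RNA were prepared in different ways, and that difference cannot be separated from the cell type in these fold changes.

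**Figure D2:**
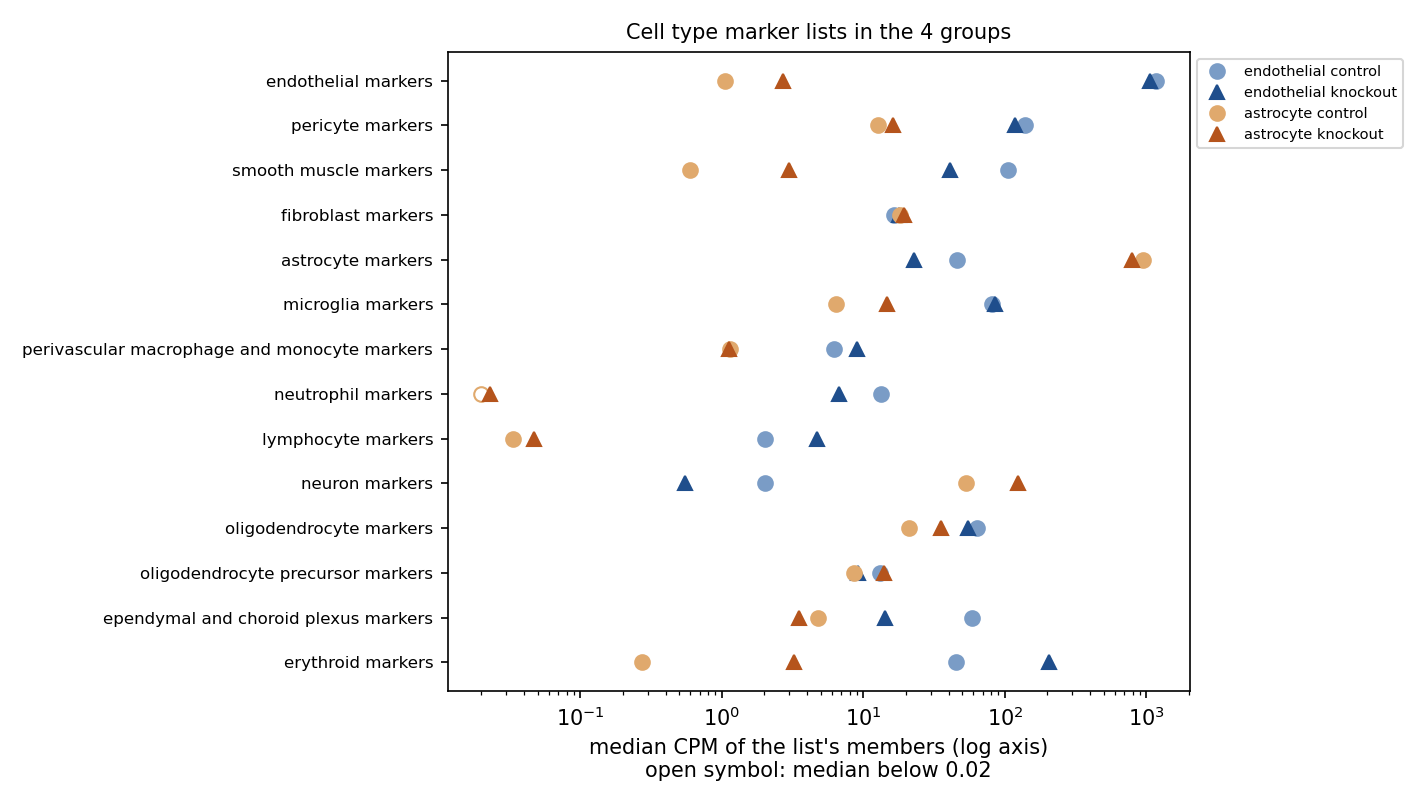
Median CPM of the members of each of the 14 cell type marker lists (log axis) in endothelial control, endothelial knockout, astrocyte control and astrocyte knockout libraries, each symbol being the median over a list's genes of the group means and the open symbol a median under 0.02. Endothelial markers have a median of 1170 CPM in endothelial controls and 1.06 in astrocyte controls, and astrocyte markers 46.1 and 946.

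The endothelial comparison asked which genes differed between knockout and control endothelial cells. Of 23 cell cycle, 31 hypoxia and glycolysis, 27 matrix and 16 coagulation genes, 18, 20, 17 and 11 rose, and of 16 arterial genes 10 fell, but no list passed camera with an estimated correlation. Without control 4 these counts were 10, 10, 8, 7 and 6. The cell cycle count was also 10 without knockout 3, the matrix count 11 without control 2 and the arterial count 6 without control 3 or knockout 3. Where leaving out 1 library moved the number of list members that rose or fell by over 1.5 times, both numbers without it stand in brackets after the count in the paragraphs on lists. The hypoxia-induced prolyl hydroxylase Egln3 rose from 2.16 ± 1.1 to 46.4 ± 7.41 CPM (control n = 3, knockout n = 4), the apelin ligand gene Apln, a tip cell gene, from 21.5 ± 8.9 to 455 ± 124 CPM, and coagulation factor V, F5, from 108 ± 15.7 to 934 ± 204 CPM. The arterial gene Gkn3 fell from 216 ± 46.8 to 11.5 ± 1.01 CPM, a log2 change of -4.22 ± 0.16 (adjusted p = 8.47e-05). Of 20391 genes tested, 3576 changed, with 1904 higher and 1672 lower, and 747 and 818 of them by at least 2-fold. Scaled by the library total alone, 44.1% of the endothelial calls were higher, against 53.2% with TMM factors, and 47.7% and 48.3% were in the fits of RPKM with a pseudocount of 1 and 0.1. In 31.1% of all genes tested the libraries of the groups did not overlap, where chance gives 5.71%. The count of changed genes was 1586 without endothelial control 4 and 2110 without endothelial knockout 3.

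Of the 10 eligible genes with the largest increases, Klk14, a kallikrein-related peptidase (7.24 ± 0.54), Cyp3a13, a cytochrome P450 (6.09 ± 0.72), Ms4a8a (5.38 ± 0.51) and AA467197 (5.37 ± 0.57) stood beside the alpha-1-antitrypsin genes Serpina1e (6.89 ± 0.64), Serpina1b (5.45 ± 0.60) and Serpina1d (5.42 ± 0.53). The Serpina1 genes are near-identical copies, so the split of reads between them is uncertain. The other 3 calls were lost when any 1 control library was left out. Col10a1, a collagen chain (7.59 ± 1.90), had an adjusted p of 0.133 without endothelial control 2, 0.109 without endothelial control 3 and 0.0954 without endothelial control 4. Gpnmb, a glycoprotein of phagocytes (6.05 ± 1.28), had 0.0895 without endothelial control 2, 0.0567 without endothelial control 3 and 0.0853 without endothelial control 4, and Arg1, the urea cycle enzyme arginase (6.03 ± 1.16), had 0.069 without endothelial control 2, 0.0542 without endothelial control 3 and 0.0564 without endothelial control 4. The 10 largest decreases were led by Gkn3, followed by Ssu2 (-3.18 ± 0.23), the synaptotagmin gene Syt15 (-2.97 ± 0.09), the orphan receptor gene Gpr21 (-2.72 ± 0.26), the matricellular gene Ccn3 (-2.68 ± 0.31), the complement regulator Susd4 (-2.65 ± 0.23) and the metalloprotease gene Tll1 (-2.49 ± 0.44). The neutrophil granule gene Ltf (-3.03 ± 0.63) had an adjusted p of 0.0638 without endothelial control 2, 0.0677 without endothelial control 4 and 0.0563 without endothelial knockout 3. Lao1, an amino acid oxidase (-2.74 ± 0.69), had 0.0944 without endothelial control 2, 0.0692 without endothelial control 4, 0.0599 without endothelial knockout 1, 0.0622 without endothelial knockout 2, 0.0754 without endothelial knockout 3 and 0.0562 without endothelial knockout 4, and the prolactin receptor Prlr (-2.52 ± 0.56) had 0.0676 without endothelial control 3 and 0.0786 without endothelial control 4. Leaving out 1 library moved the fold by over 1.5 times for 7 of these genes. The log2 change of Col10a1 was 5.25 without knockout 3, which held 81.2 CPM against 2.43 to 9.3 in the other 3 knockouts, and 8.96 without control 4. Gpnmb had 4.86 without knockout 2 and 6.67 without control 3, AA467197 6.28 without control 4, Ms4a8a 6.11 and Serpina1b 6.37 without control 3, and Lao1 -1.69 and Tll1 -1.80 without control 2.

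Of 23 cell cycle genes, 18 rose, 0 fell and 5 did not pass the test (10 and 0 without control 4 or knockout 3). Cell cycle genes had 19 members higher and 0 lower adjusted over the list alone (camera adjusted p = 1.96e-12, and adjusted p = 0.279 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose by 2.77 ± 0.27, the mitotic kinase gene Cdk1 by 2.09 ± 0.30 and the kinetochore motor gene Cenpe by 1.91 ± 0.23. Among 31 hypoxia and glycolysis genes, 20 rose, 3 fell and 8 did not pass the test (10 and 2 without control 4, 16 and 1 without knockout 3). Hypoxia and glycolysis genes had 22 members higher and 3 lower adjusted over the list alone (camera adjusted p = 1.81e-09, and adjusted p = 0.279 with an estimated correlation). Besides Egln3 (4.40 ± 0.35), the lactate transporter Slc16a3 rose by 2.93 ± 0.25, Ankrd37 by 2.16 ± 0.19 and the glycolytic enzyme Tpi1 by 1.02 ± 0.09. Matrix genes gave a similar count: of 27, 17 rose, 0 fell and 10 did not pass the test (11 and 0 without control 2, 8 and 0 without control 4). Basement membrane and interstitial matrix genes had 18 members higher and 0 lower adjusted over the list alone (camera adjusted p = 2.81e-10, and adjusted p = 0.309 with an estimated correlation). Fibronectin, Fn1, rose from 4391 ± 63 to 11973 ± 744 CPM, and the lysyl oxidase gene Loxl2, Col6a2 and Postn rose by 2.29 ± 0.22, 1.42 ± 0.17 and 1.92 ± 0.25. Mitochondrial transcripts made up 4.325, 3.091 and 4.42% of counts in endothelial controls 2, 3 and 4 and 2.589, 3.755, 2.528 and 2.504% in endothelial knockouts 1 to 4. In the same libraries the fibroblast collagen gene Col3a1 rose by 3.06 ± 0.34, and erythroid markers had a median of 2.20 with none passing the test.

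Coagulation and fibrinolysis genes were mostly higher. Of 16, 11 rose, 1 fell and 4 did not pass the test (9 and 0 without control 2, 7 and 0 without control 4). Coagulation and fibrinolysis genes had 11 members higher and 2 lower adjusted over the list alone (camera adjusted p = 8.38e-10, and adjusted p = 0.18 with an estimated correlation). F5 rose by 3.12 ± 0.21, the tissue factor pathway inhibitor Tfpi by 1.71 ± 0.12 and the annexin partner S100a10 by 1.51 ± 0.09. In the list around the transcription factors Klf2 and Klf4, 15 genes were measured: 6 rose, 1 fell and 8 did not pass the test (5 and 0 without control 3, 3 and 0 without control 4). The Klf2 and Klf4 list had 10 members higher and 1 lower adjusted over the list alone (camera adjusted p = 2.39e-05, and adjusted p = 0.369 with an estimated correlation). Thrombomodulin, Thbd, rose from 585 ± 149 to 1578 ± 187 CPM, the ligand gene Wnt9b by 4.71 ± 0.63 (5.75 without control 3) and the matrix protease gene Adamts9 by 1.14 ± 0.16, while Klf2 (0.17 ± 0.16) and Klf4 (0.61 ± 0.20), chosen after their values were seen, did not pass the test. Angiogenesis and tip cell genes went both ways: of 23, 9 rose, 4 fell and 10 did not pass the test (8 and 1 without control 3, 6 and 1 without control 4, 9 and 2 without knockout 1). Angiogenesis and tip cell genes had 10 members higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0254, and adjusted p = 0.721 with an estimated correlation). Apln rose by 4.41 ± 0.38, the vessel-destabilising ligand Angpt2 by 2.69 ± 0.19, Angpt1 by 1.51 ± 0.13 and adrenomedullin, Adm, by 2.16 ± 0.21. The median of that list was -0.03, its mean 0.58 and its set test pointed up. Leukocyte adhesion and chemokine genes numbered 24: 7 rose, 0 fell and 17 did not pass the test (3 and 0 without control 4). Leukocyte adhesion and chemokine genes had 10 members higher and 0 lower adjusted over the list alone (camera adjusted p = 3.85e-07, and adjusted p = 0.279 with an estimated correlation). The NF-kappaB inhibitor gene Tnfaip3, Cx3cl1 and Vcam1, an adhesion receptor for leukocytes, rose by 1.24 ± 0.08, 0.58 ± 0.08 and 0.44 ± 0.09.

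Of 16 arterial genes, 0 rose, 10 fell and 6 did not pass the test (0 and 6 without control 3, control 4 or knockout 3). Arterial endothelial genes had 0 members higher and 11 lower adjusted over the list alone (camera adjusted p = 1.88e-10, and adjusted p = 0.309 with an estimated correlation). Gkn3, the gap junction genes Gja5 (-1.95 ± 0.18) and Gja4 (-1.18 ± 0.11) and the Notch target Hey1 (-1.82 ± 0.21) had the smallest p-values. Smooth muscle markers fell beside them: of 7, 0 rose, 6 fell and 1 did not pass the test. Smooth muscle markers had 0 members higher and 6 lower adjusted over the list alone (camera adjusted p = 9.1e-09, and adjusted p = 0.279 with an estimated correlation). Acta2 and the smooth muscle myosin Myh11 fell from 596 ± 60.8 to 238 ± 29.5 CPM and from 603 ± 74.2 to 243 ± 42.7 CPM. Among 14 venous genes, 5 rose, 1 fell and 8 did not pass the test (3 and 1 without control 2 or control 3, 1 and 0 without control 4, 3 and 0 without knockout 1 or knockout 3, 4 and 0 without knockout 4). Venous endothelial genes had 5 members higher and 3 lower adjusted over the list alone (camera adjusted p = 0.257). The median of this list was positive (0.05), its mean negative (-0.01) and its set test pointed up, and Vcam1 was among the members that rose. Blood-brain barrier genes numbered 27: 4 rose, 5 fell and 18 did not pass the test (2 and 4 without control 2, 5 and 3 without control 3, 2 and 3 without control 4 or knockout 3). Blood-brain barrier genes had 5 members higher and 5 lower adjusted over the list alone (camera adjusted p = 0.632). Itm2a (-1.43 ± 0.16), the organic anion transporter Slc22a8 (-1.19 ± 0.13) and the Wnt-pathway transcription factor Lef1 (-0.70 ± 0.10) fell, and Pglyrp1 (1.54 ± 0.16) rose. Of 21 endothelial-to-mesenchymal genes, 6 rose, 2 fell and 13 did not pass the test (5 and 1 without control 3, 3 and 1 without control 4, 4 and 1 without knockout 3). Endothelial-to-mesenchymal genes had 8 members higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0801). The transcription factor Snai1 rose by 1.28 ± 0.21 and the ligand gene Tgfb2 changed by -1.70 ± 0.21.

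Of 15 complement genes, 1 rose, 1 fell and 13 did not pass the test (2 and 1 without control 2, 1 and 0 without control 4, knockout 1, knockout 2, knockout 3 or knockout 4). Complement genes had 2 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.308). The complement inhibitor Cd55 rose from 14.6 ± 2.94 to 131 ± 4.21 CPM. Of 20 interferon response genes, 2 rose, 1 fell and 17 did not pass the test (1 and 0 without control 2 or control 4, 2 and 0 without knockout 4). Interferon response genes had 2 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.43), led by Ifi27l2a (2.48 ± 0.35). For 17 antigen presentation genes, 0 rose, 0 fell and 17 did not pass the test (1 and 0 without knockout 1, 0 and 1 without knockout 2). Antigen presentation genes had 0 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.628). The class II activator Ciita had 1.88 ± 0.62. For 11 CCM complex genes, 1 rose, 1 fell and 9 did not pass the test (0 and 1 without control 2 or control 4, 3 and 1 without control 3, 2 and 1 without knockout 2). CCM complex genes had 4 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.308), with Mapk7 (0.30 ± 0.06) the member that rose and Pdcd10 the one that fell. The adjusted p of Mapk7 was 0.0565 without endothelial control 2 and 0.0716 without endothelial control 4. For 22 cholesterol synthesis genes, 1 rose, 2 fell and 19 did not pass the test (0 and 1 without control 2, control 4, knockout 1 or knockout 2, 0 and 0 without control 3 or knockout 3). Cholesterol synthesis genes had 1 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.283). For 18 iron and heme handling genes, 1 rose, 1 fell and 16 did not pass the test (1 and 0 without control 2, 0 and 1 without control 3 or knockout 1, 0 and 0 without control 4 or knockout 3, 3 and 1 without knockout 2, 2 and 0 without knockout 4). Iron and heme handling genes had 1 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.674). The immediate early and dissociation list had 18 members: 0 rose, 1 fell and 17 did not pass the test (1 and 1 without knockout 2, 0 and 2 without knockout 4). Immediate early and dissociation genes had 0 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.632). The heat shock gene Hspa1a was the 1 that changed, by -0.60 ± 0.10. The disease-associated microglia list had 15: 4 rose, 0 fell and 11 did not pass the test (1 and 0 without control 2, control 3 or control 4, 2 and 0 without knockout 3). Disease-associated microglia genes had 5 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00971, and adjusted p = 0.74 with an estimated correlation). The tetraspanin Cd9, which endothelial cells also express, rose by 1.10 ± 0.09. Of the 13 pan-reactive astrocyte genes, 2 rose, 2 fell and 9 did not pass the test (1 and 1 without control 2, 1 and 2 without control 3, 0 and 0 without control 4, 4 and 2 without knockout 1, 2 and 1 without knockout 2, 1 and 0 without knockout 3 or knockout 4). Pan-reactive astrocyte genes had 4 members higher and 4 lower adjusted over the list alone (camera adjusted p = 0.867). Of the 11 A1 reactive astrocyte genes, 1 rose, 2 fell and 8 did not pass the test (1 and 1 without control 2 or control 4). A1 reactive astrocyte genes had 2 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.544), including the proteoglycan gene Srgn at 0.87 ± 0.11. Of the 12 A2 reactive astrocyte genes, 3 rose, 1 fell and 8 did not pass the test (1 and 1 without control 4). A2 reactive astrocyte genes had 3 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0487, and adjusted p = 0.377 with an estimated correlation), including S100a10 at 1.51 ± 0.09. Means of the pan-reactive and A1 lists were below 0, at -0.00013 and -0.0037, while their medians, 0.12 and 0.14, were above it.

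Markers of accompanying cells changed as well in the endothelial fraction. Astrocyte markers fell in part: of 17, 0 rose, 8 fell and 9 did not pass the test (0 and 3 without control 4 or knockout 3, 0 and 5 without knockout 1). Astrocyte markers had 0 members higher and 10 lower adjusted over the list alone (camera adjusted p = 6.91e-06, and adjusted p = 0.212 with an estimated correlation). The sodium pump subunit gene Atp1b2 and the glutamate transporter gene Slc1a3 changed by -0.63 ± 0.08 and -1.23 ± 0.22 on the log2 scale. Ependymal and choroid plexus markers numbered 7: 0 rose, 4 fell and 3 did not pass the test (0 and 2 without control 3 or control 4). Ependymal and choroid plexus markers had 0 members higher and 7 lower adjusted over the list alone (camera adjusted p = 5.51e-05, and adjusted p = 0.18 with an estimated correlation), including the folate receptor gene Folr1 at -1.83 ± 0.26. Among 11 neuron markers, 0 rose, 4 fell and 7 did not pass the test (0 and 1 without control 2 or knockout 1, 0 and 0 without control 4 or knockout 3). Neuron markers had 0 members higher and 7 lower adjusted over the list alone (camera adjusted p = 0.000247, and adjusted p = 0.454 with an estimated correlation). Pericyte markers numbered 9: 4 rose, 0 fell and 5 did not pass the test (2 and 0 without control 4). Pericyte markers had 4 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0315, and adjusted p = 0.669 with an estimated correlation). The potassium channel genes Abcc9 and Kcnj8 rose by 1.69 ± 0.22 and 1.54 ± 0.22. Of 12 endothelial markers, 0 rose, 1 fell and 11 did not pass the test (0 and 0 without control 3, control 4 or knockout 1). The call was Flt1, a receptor for vascular endothelial growth factor (-0.64 ± 0.16), whose adjusted p was 0.0878 without endothelial control 3, 0.13 without endothelial control 4, 0.0557 without endothelial knockout 1 and 0.087 without endothelial knockout 3, and 0.0823 with all 13 libraries in 1 fit. Endothelial markers had 0 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.647). For fibroblast markers (8), 1 rose, 0 fell and 7 did not pass the test (2 and 0 without knockout 1, 2 and 1 without knockout 3). Fibroblast markers had 3 members higher and 3 lower adjusted over the list alone (camera adjusted p = 0.491). For perivascular macrophage and monocyte markers (9), 1 rose, 0 fell and 8 did not pass the test (0 and 0 without control 3, control 4 or knockout 3, 2 and 0 without knockout 1, 1 and 2 without knockout 2). Perivascular macrophage and monocyte markers had 1 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.68), and the median of -0.11 and the mean of 0.33 differed in sign. For neutrophil markers (9), 0 rose, 3 fell and 6 did not pass the test (0 and 0 without control 2, control 4, knockout 1, knockout 2, knockout 3 or knockout 4, 0 and 5 without control 3). Neutrophil markers had 0 members higher and 3 lower adjusted over the list alone (camera adjusted p = 0.369). None of the 12 microglia, 12 lymphocyte, 9 oligodendrocyte, 6 oligodendrocyte precursor and 7 erythroid markers passed the edgeR test over all genes. Leaving out knockout 2, 5 microglia markers fell, and 3 lymphocyte and 1 erythroid markers rose. Leaving out knockout 1, 1 lymphocyte and 2 erythroid markers rose, without knockout 3, 1 oligodendrocyte precursor marker fell, and without knockout 4, 2 oligodendrocyte markers fell and 2 erythroid markers rose. Adjusted over the list alone, 0, 0, 0, 0 and 4 of them did, with camera adjusted p-values of 0.411, 0.00971, 0.325, 0.257 and 0.0315 and, for lymphocyte and erythroid markers, adjusted p = 0.74 with an estimated correlation. At these list sizes no list in the endothelial comparison passed camera with an estimated correlation, against 17 of 36 with the preset correlation.

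**Figure D3:**
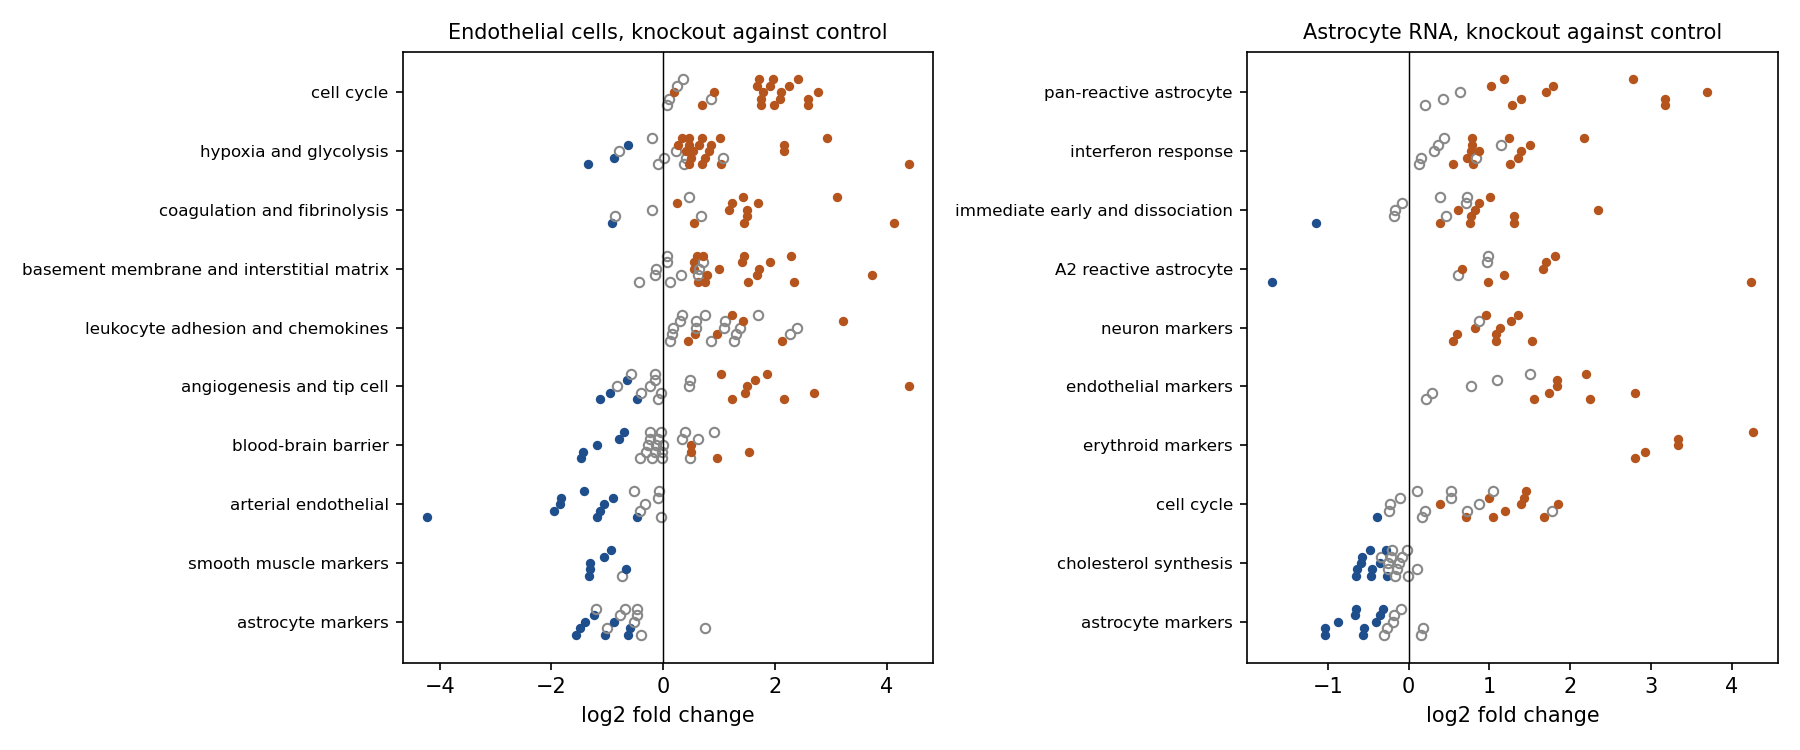
Log2 change of each measured member of 10 gene lists in endothelial cells (left) and of 10 lists in astrocyte RNA (right), knockout against control. Filled orange points rose, filled blue points fell and open grey points did not pass at an adjusted p of 0.05 by edgeR; arterial genes lie at or below -0.04 in endothelial cells, and all 5 erythroid markers lie at or above 2.80 in astrocyte RNA.

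The astrocyte comparison asked which ribosome-bound RNAs of astrocytes differed when Pdcd10 was deleted under the endothelial promoter. Of 13 pan-reactive astrocyte, 20 interferon and 18 immediate early genes, 10, 13 and 10 rose, and 10 of 22 cholesterol synthesis genes and 10 of 17 astrocyte markers fell, but no list passed camera with an estimated correlation. The interferon count was 7 without control 2 and 8 without control 3 or knockout 3, and the immediate early count was 6 without control 3. Gfap, an intermediate filament of reactive astrocytes, rose from 6695 ± 743 to 16191 ± 2282 CPM (n = 3 each), a log2 change of 1.27 ± 0.13 (adjusted p = 0.000948). App, the amyloid precursor protein gene, rose from 202 ± 23.6 to 2277 ± 131 CPM (3.49 ± 0.11, adjusted p = 8.31e-06). The sphingosine-1-phosphate receptor gene S1pr3 rose from 2.45 ± 0.456 to 31.5 ± 7.86 CPM. Tsc22d3, which encodes a glucocorticoid-induced leucine zipper protein, fell from 1737 ± 331 to 326 ± 38.5 CPM. Of 18701 genes tested, 3801 changed, with 2102 higher and 1699 lower, and 990 and 173 of them by at least 2-fold. Scaled by the library total alone, 72.4% of the calls were higher, against 55.3% with TMM factors, and 65.4% and 65.6% were in the RPKM fits. In 40.5% of all genes tested the libraries of the groups did not overlap, where chance gives 10%. The count of changed genes was 1556 without astrocyte control 2, 1975 without astrocyte control 3 and 2524 without astrocyte knockout 3.

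**Figure D4:**
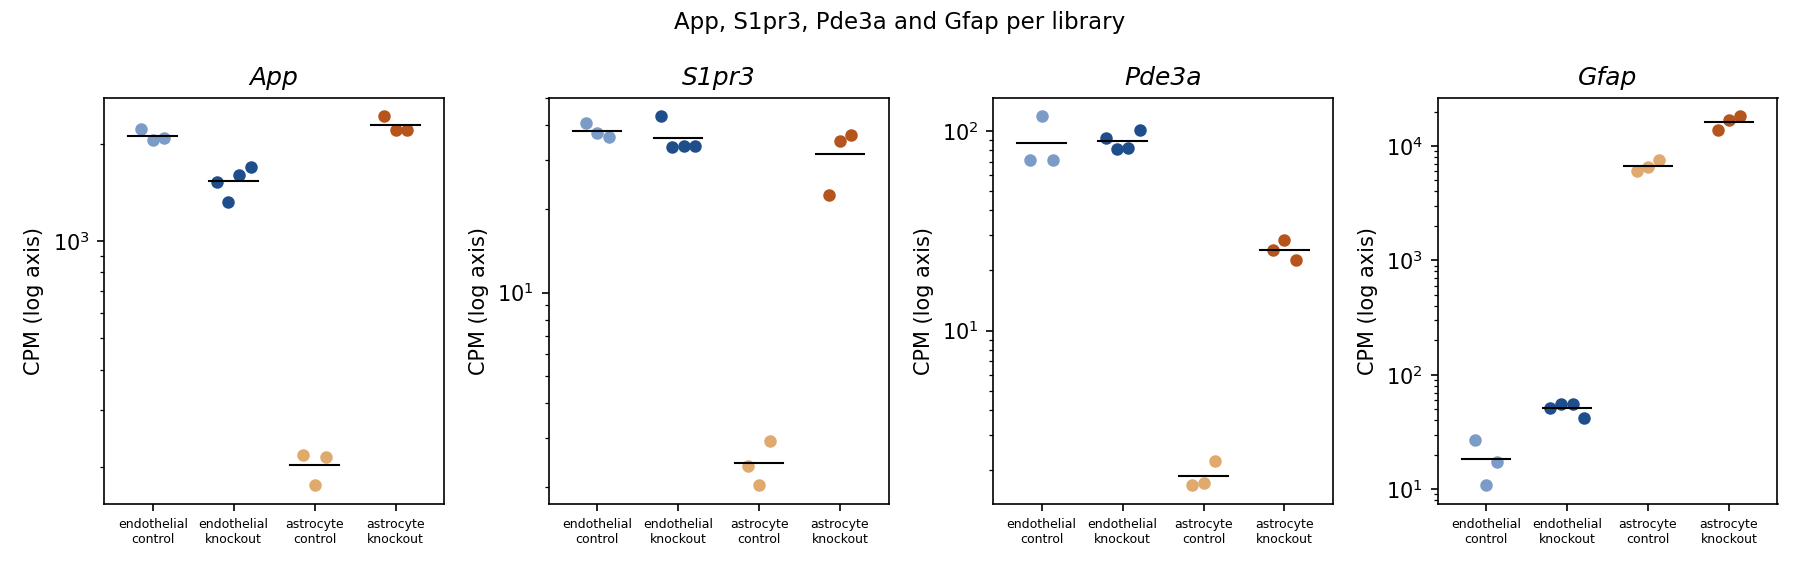
TMM-scaled CPM of App, S1pr3, Pde3a and Gfap in each library (points, log axis), with group means as horizontal lines. App lies at a mean of 202 ± 23.6 CPM (SD, n = 3) in astrocyte controls and 2277 ± 131 in astrocyte knockouts, and at 2119 ± 85.3 and 1534 ± 162 in endothelial controls and knockouts.

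The 10 largest increases among eligible genes in astrocyte RNA included Ndufa4l2, a hypoxia-induced mitochondrial protein (4.84 ± 0.42), the collagen gene Col14a1 (4.62 ± 0.68), the receptor gene Eda2r (3.81 ± 0.32), the phosphodiesterase gene Pde3a (3.77 ± 0.16), S1pr3 (3.69 ± 0.23), the collagen cross-linking enzyme Lox (3.51 ± 0.55), App, the mucin gene Glycam1 (3.39 ± 0.31) and von Willebrand factor, Vwf (3.39 ± 0.49). The haemoglobin gene Hba-a2 (4.27 ± 1.09), which shares reads with Hba-a1, had an adjusted p of 0.0934 without astrocyte control 1, 0.096 without astrocyte control 2, 0.1 without astrocyte control 3, 0.114 without astrocyte knockout 2 and 0.0689 without astrocyte knockout 4. The 10 largest decreases were the choroid plexus gene Ttr (-3.86 ± 0.58), the hypoxia-inducible factor gene Hif3a (-2.66 ± 0.24), Nrros (-2.44 ± 0.29), the transcription factor Zbtb16 (-2.43 ± 0.26), Tsc22d3 (-2.42 ± 0.16), the Wnt receptor Fzd2 (-2.36 ± 0.24), the lipid transporter Mfsd2a (-2.16 ± 0.26), Tmem52 (-2.14 ± 0.35) and a pair whose calls were lost when any 1 knockout library was left out. The lipid droplet gene Plin4 (-2.87 ± 0.65) had an adjusted p of 0.145 without astrocyte knockout 2, 0.0684 without astrocyte knockout 3 and 0.0529 without astrocyte knockout 4, and Arl4d (-2.64 ± 0.58) had 0.0815 without astrocyte knockout 2, 0.0576 without astrocyte knockout 3 and 0.0701 without astrocyte knockout 4. Hif3a had an adjusted p of 0.056 with all 13 libraries in 1 fit. The fold moved by over 1.5 times for Col14a1 (6.02) and Plin4 (-1.84) without control 2, Lox (4.23) and Ttr (-3.20) without control 3, Arl4d (-1.90) without control 1 and Hba-a2 (3.62) without knockout 4.

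Of 13 pan-reactive astrocyte genes, 10 rose, 0 fell and 3 did not pass the test. Pan-reactive astrocyte genes had 10 members higher and 0 lower adjusted over the list alone (camera adjusted p = 6.16e-15, and adjusted p = 0.202 with an estimated correlation). S1pr3, the intermediate filament gene Vim (1.78 ± 0.14), the chemokine gene Cxcl10 (3.17 ± 0.30) and Gfap had the smallest p-values. The A2 list had 11 members measured: 7 rose, 1 fell and 3 did not pass the test (4 and 1 without control 2). A2 reactive astrocyte genes had 10 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000138, and adjusted p = 0.271 with an estimated correlation), among them the transglutaminase gene Tgm1 (4.23 ± 0.58) and Cd109 (1.66 ± 0.26). Sphk1 changed by -1.70 ± 0.26. In the A1 list of 11, 3 rose, 1 fell and 7 did not pass the test (2 and 0 without control 1 or control 2, 3 and 0 without knockout 2 or knockout 3). A1 reactive astrocyte genes had 3 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0413, and adjusted p = 0.424 with an estimated correlation). The galactosyltransferase gene Ggta1 and the guanylate-binding gene Gbp2 rose by 1.77 ± 0.21 and 1.39 ± 0.20. Interferon response genes numbered 20: 13 rose, 0 fell and 7 did not pass the test (7 and 0 without control 2, 8 and 0 without control 3 or knockout 3). Interferon response genes had 14 members higher and 0 lower adjusted over the list alone (camera adjusted p = 1.38e-07, and adjusted p = 0.226 with an estimated correlation), including Irf9 (0.80 ± 0.10), Gbp2, Ifit2 (0.78 ± 0.12) and Isg15 (1.25 ± 0.20). Of 17 antigen presentation genes, 6 rose, 0 fell and 11 did not pass the test (5 and 1 without control 1). Antigen presentation genes had 7 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00048, and adjusted p = 0.274 with an estimated correlation), led by the class II genes H2-Ab1 (2.01 ± 0.26) and Cd74 (2.55 ± 0.36). Complement genes numbered 14: 5 rose, 0 fell and 9 did not pass the test (3 and 0 without control 1, 2 and 0 without control 2 or control 3, 3 and 1 without knockout 4). Complement genes had 7 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000798, and adjusted p = 0.424 with an estimated correlation). C3 rose by 1.51 ± 0.25. Microglia markers rose in part in the same libraries: of 12, 5 rose, 0 fell and 7 did not pass the test (3 and 0 without control 2, control 3 or knockout 2, 3 and 1 without knockout 4). Microglia markers had 8 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000152, and adjusted p = 0.406 with an estimated correlation). The receptor genes Cx3cr1 and Csf1r rose from 4.78 ± 0.501 to 13.6 ± 2.54 CPM and from 15.5 ± 2.35 to 35.9 ± 7.09 CPM. With all 13 libraries in 1 fit, the adjusted p was 0.136 for H2-Ab1, 0.0556 for Cd74, 0.069 for C3, 0.166 for Cx3cr1 and 0.241 for Csf1r.

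Genes of immediate early and metabolic programmes also moved. Of 18 immediate early and dissociation genes, 10 rose, 1 fell and 7 did not pass the test (8 and 0 without control 2, knockout 2 or knockout 4, 6 and 0 without control 3, 9 and 0 without knockout 3). Immediate early and dissociation genes had 12 members higher and 1 lower adjusted over the list alone (camera adjusted p = 2.93e-06, and adjusted p = 0.226 with an estimated correlation). The transcription factor genes Junb and Jun rose by 1.30 ± 0.08 and 0.88 ± 0.08. Of 22 cholesterol synthesis genes, 0 rose, 10 fell and 12 did not pass the test. Cholesterol synthesis genes had 0 members higher and 10 lower adjusted over the list alone (camera adjusted p = 2.3e-05, and adjusted p = 0.202 with an estimated correlation). The squalene synthase gene Fdft1 changed by -0.59 ± 0.07, Tm7sf2 by -0.63 ± 0.08, Insig1 by -0.65 ± 0.09 and Sqle by -0.45 ± 0.07. Of 17 astrocyte markers, 0 rose, 10 fell and 7 did not pass the test. Astrocyte markers had 0 members higher and 11 lower adjusted over the list alone (camera adjusted p = 2.41e-08, and adjusted p = 0.226 with an estimated correlation). The connexin genes Gjb6 and Gja1 changed by -1.03 ± 0.11 and -0.87 ± 0.11, Glul by -0.65 ± 0.08 and Slc1a2 by -0.66 ± 0.09. Among 31 hypoxia and glycolysis genes, 14 rose, 4 fell and 13 did not pass the test (9 and 2 without control 2). Hypoxia and glycolysis genes had 14 members higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00343, and adjusted p = 0.226 with an estimated correlation). The glycolytic regulators Pdk1, Pfkl and Ldha rose by 0.85 ± 0.08, 0.54 ± 0.07 and 0.58 ± 0.07. Cell cycle genes numbered 23: 10 rose, 1 fell and 12 did not pass the test (6 and 1 without control 1 or control 3, 3 and 0 without control 2, 4 and 1 without knockout 3, 5 and 1 without knockout 4). Cell cycle genes had 11 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00254, and adjusted p = 0.282 with an estimated correlation), including Tpx2 (1.0 ± 0.16) and Top2a (1.45 ± 0.26). Iron and heme handling genes numbered 17: 5 rose, 0 fell and 12 did not pass the test (2 and 0 without control 2, 4 and 1 without knockout 3 or knockout 4). Iron and heme handling genes had 5 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0618), and transferrin, Trf, and heme oxygenase, Hmox1, rose by 1.5 ± 0.13 and 1.08 ± 0.14. In the fit of all 13 libraries, Glul, Slc1a2 and Hmox1 had an adjusted p of 0.0716, 0.323 and 0.17.

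Vascular gene lists were partly higher in astrocyte RNA, at low levels. Endothelial markers rose in part: of 12, 7 rose, 0 fell and 5 did not pass the test (2 and 0 without control 2, 1 and 0 without control 3). Endothelial markers had 8 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000225, and adjusted p = 0.424 with an estimated correlation). The angiopoietin receptor Tek rose from 0.339 ± 0.0525 to 1.58 ± 0.912 CPM, with an adjusted p of 0.0505 without control 3 and knockout 4 together. Erythroid markers rose most: of 5, 5 rose, 0 fell and 0 did not pass the test. Erythroid markers had 5 members higher and 0 lower adjusted over the list alone (camera adjusted p = 4.19e-11, and adjusted p = 0.202 with an estimated correlation), with a median log2 change of 3.33, and Hbb-bs rose from 1.66 ± 0.25 to 16.8 ± 5.26 CPM. The near-identical haemoglobin copies share reads, so the split between them is uncertain. Smooth muscle markers numbered 7: 5 rose, 0 fell and 2 did not pass the test. Smooth muscle markers had 6 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000101, and adjusted p = 0.271 with an estimated correlation), and calponin, Cnn1, rose from 0.34 ± 0.133 to 2.91 ± 0.687 CPM. Pericyte markers numbered 9: 3 rose, 0 fell and 6 did not pass the test (1 and 0 without control 2, control 3 or knockout 3). Pericyte markers had 3 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00781, and adjusted p = 0.274 with an estimated correlation). Rgs5 rose from 3.48 ± 0.966 to 23.7 ± 6.42 CPM. Beside these markers, matrix genes numbered 27: 12 rose, 2 fell and 13 did not pass the test (4 and 1 without control 1, 6 and 0 without control 2, 5 and 0 without control 3, 9 and 0 without knockout 2, 10 and 0 without knockout 3). Basement membrane and interstitial matrix genes had 12 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00048, and adjusted p = 0.482 with an estimated correlation), led by Mmp2 (1.74 ± 0.21). Venous genes numbered 13: 6 rose, 0 fell and 7 did not pass the test (6 and 2 without knockout 4). Venous endothelial genes had 6 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000957, and adjusted p = 0.406 with an estimated correlation), led by the adhesion receptor Icam1 (2.71 ± 0.28). Arterial genes numbered 15: 3 rose, 1 fell and 11 did not pass the test (3 and 2 without control 1 or knockout 4). Arterial endothelial genes had 5 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.411 with an estimated correlation), including the neuronal gene Stmn2 (0.79 ± 0.10) and Notch1 (-0.63 ± 0.11). Angiogenesis and tip cell genes numbered 21: 7 rose, 0 fell and 14 did not pass the test (3 and 0 without control 2). Angiogenesis and tip cell genes had 8 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00048, and adjusted p = 0.226 with an estimated correlation). Adm rose by 1.83 ± 0.23. Coagulation genes numbered 16: 7 rose, 1 fell and 8 did not pass the test (7 and 2 without knockout 4). Coagulation and fibrinolysis genes had 7 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00828, and adjusted p = 0.467 with an estimated correlation), and tissue factor, F3, fell from 274 ± 25.8 to 137 ± 11.3 CPM. Blood-brain barrier genes numbered 26: 9 rose, 3 fell and 14 did not pass the test (4 and 1 without control 2, 5 and 1 without control 3, 9 and 1 without knockout 2). Blood-brain barrier genes had 11 members higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0837). Mfsd2a fell from 225 ± 69.1 to 50.6 ± 12.7 CPM.

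The remaining lists were as follows in astrocyte RNA. Neuron markers rose nearly throughout: of 11, 10 rose, 0 fell and 1 did not pass the test (4 and 0 without control 2 or control 3). Neuron markers had 11 members higher and 0 lower adjusted over the list alone (camera adjusted p = 1.23e-08, and adjusted p = 0.274 with an estimated correlation). The synaptic genes Syp and Syt1 rose from 80.6 ± 4.36 to 194 ± 39.1 CPM and from 129 ± 12.2 to 274 ± 60.02 CPM. Oligodendrocyte precursor markers numbered 8: 2 rose, 0 fell and 6 did not pass the test (1 and 0 without control 1, control 2, knockout 2 or knockout 3). Oligodendrocyte precursor markers had 3 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.274 with an estimated correlation). Olig1, which astrocytes also expressed at 356 ± 6.71 CPM in controls, rose by 0.80 ± 0.07. Oligodendrocyte markers numbered 9: 1 rose, 0 fell and 8 did not pass the test (0 and 0 without control 2 or control 3, 4 and 0 without knockout 4). Oligodendrocyte markers had 2 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0451, and adjusted p = 0.482 with an estimated correlation). Ependymal and choroid plexus markers numbered 7: 1 rose, 2 fell and 4 did not pass the test (1 and 1 without control 2, control 3, knockout 2, knockout 3 or knockout 4). Ependymal and choroid plexus markers had 1 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.217), the cilia regulator Foxj1 rising by 1.35 ± 0.15 while Ttr fell from 37.8 ± 24.4 to 2.56 ± 1.43 CPM. For leukocyte adhesion and chemokine genes (12 measured), 6 rose, 1 fell and 5 did not pass the test. Leukocyte adhesion and chemokine genes had 6 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000735, and adjusted p = 0.274 with an estimated correlation), led by Cxcl10 and Icam1 (2.71 ± 0.28). For endothelial-to-mesenchymal genes (21), 7 rose, 2 fell and 12 did not pass the test (3 and 2 without control 1, 3 and 1 without control 2, 4 and 1 without control 3, 6 and 1 without knockout 2 or knockout 3). Endothelial-to-mesenchymal genes had 7 members higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0413, and adjusted p = 0.492 with an estimated correlation), led by Vim. For the Klf2 and Klf4 list (14), 5 rose, 1 fell and 8 did not pass the test. The Klf2 and Klf4 list had 8 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0093, and adjusted p = 0.424 with an estimated correlation). Adamts9 changed by -1.11 ± 0.18. For disease-associated microglia genes (13), 4 rose, 1 fell and 8 did not pass the test (3 and 4 without knockout 4). Disease-associated microglia genes had 4 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.183), the galectin gene Lgals3 rising by 1.70 ± 0.19 and Axl changing by -0.81 ± 0.10. Syt1, Olig1 and Axl had an adjusted p of 0.0549, 0.316 and 0.0675 with all 13 libraries in 1 fit. For CCM complex genes (11), 0 rose, 2 fell and 9 did not pass the test (0 and 1 without control 1, control 2, control 3, knockout 2 or knockout 3). CCM complex genes had 0 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.147). For lymphocyte markers (5), 2 rose, 0 fell and 3 did not pass the test (2 and 1 without control 1, 1 and 0 without control 2, knockout 2 or knockout 3, 0 and 0 without control 3, 1 and 1 without knockout 4). Lymphocyte markers had 2 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.393). For fibroblast markers (8), 0 rose, 1 fell and 7 did not pass the test (0 and 0 without control 2 or control 3, 1 and 0 without knockout 2, 0 and 2 without knockout 4). Fibroblast markers had 0 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.68). For perivascular macrophage and monocyte markers (8), 0 rose, 0 fell and 8 did not pass the test (0 and 1 without control 1 or knockout 4). Perivascular macrophage and monocyte markers had 0 members higher and 0 lower adjusted over the list alone (camera adjusted p = 0.683). The neutrophil list had 1 measured member, Mmp9, with 0.77 ± 0.42, which did not pass the test over all genes or adjusted over the list alone. No list in the astrocyte comparison passed camera with an estimated correlation, against 27 of 35 with the preset correlation.

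The test of the difference between the fractions asked for which genes the knockout change was not the same in endothelial cells and astrocyte RNA. App had a change of 3.49 ± 0.11 in astrocyte RNA and -0.47 ± 0.12 in endothelial cells and S1pr3 3.69 ± 0.23 and -0.09 ± 0.10, with differences, endothelial minus astrocyte, of -4.0 ± 0.16 (adjusted p = 2.32e-07) and -3.82 ± 0.24 (adjusted p = 9.98e-06). Syt15 had a change of -2.97 ± 0.09 in endothelial cells and 2.69 ± 0.27 in astrocyte RNA, a difference of -5.71 ± 0.24 (adjusted p = 2.32e-07). The remaining genes among the 10 with the smallest p-values were Prr5 (3.47 ± 0.20), the kinase gene Map3k20 (-1.71 ± 0.11), the anion exchanger Slc4a3 (-2.04 ± 0.13), the delta-catenin gene Ctnnd2 (3.21 ± 0.21), the sulfotransferase gene Chst1 (3.36 ± 0.22), Tmcc1 (1.23 ± 0.08) and Pde3a (-3.79 ± 0.27). Of 22057 genes tested over the 13 libraries, 3255 differed in their change, 1174 with a higher and 2081 with a lower change in endothelial cells. Scaled by the library total alone, 25.1% of these calls had the higher change in endothelial cells, against 36.1% with TMM factors. The count was 2085 without astrocyte control 2.

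Changes shared by the fractions were counted last, over the 17192 genes tested in both. Vwf rose in both, by 1.18 ± 0.21 in endothelial cells (adjusted p = 0.0503 without control 4) and 3.39 ± 0.49 in astrocyte RNA. Adm rose by 2.16 ± 0.21 and 1.83 ± 0.23 and Pglyrp1 by 1.54 ± 0.16 and 2.99 ± 0.48 (3.71 in astrocyte RNA without control 2), while Pdcd10 fell in both. There were 360 genes higher in both, where independent lists would share 191, and 254 lower in both, against 145. Higher in endothelial cells and lower in astrocyte RNA were 116, against 163, and the reverse held for 229, against 170. Fisher's exact test, two-sided, gave p = 3.14e-36, 1.93e-20, 2.94e-05 and 1.07e-06 in that order. Genes are not independent replicates, so neither these p-values nor the expected counts measure replication over libraries. Endothelial markers also rose in astrocyte RNA, so endothelial RNA may account for some genes higher in both, which was not tested. The comparisons shared no library, and across genes their log2 changes had a Pearson r of 0.123 and a Spearman rho of 0.0797.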

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

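Of the tests in this part, those on neuron RNA, endothelial RNA and the neighbours of App were chosen only after the result was seen. Among 122 values (genes the rule takes, and the total count) tested for a single endothelial knockout library lying apart from the other 3, 12 did so, and chance flags about 1 in 20 groups. They fell on knockout 1 for 4 genes, knockout 2 for 4, knockout 3 for 3 and knockout 4 for 1, and genes of 1 cell type are not independent of each other. The measure was the gap to the nearest other library as a share of the whole range.

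Immune cell genes stood apart in knockout 2: Tmem119 (gap 0.895) at 73.6 CPM against 9.73 to 16.4 in the others, P2ry12 (0.875) at 85.8 against 8.99 to 18.6 and the B cell gene Ms4a1 (0.841) at 16.7 against 2.04 to 4.37. The astrocyte gene Slc1a3 (0.904) was also highest there, at 31.5 CPM against 19.6 to 20.7. In knockout 3, Col10a1 (0.913) stood at 81.2 CPM against 2.43 to 9.3, Loxl2 (0.871) at 39 against 22.7 to 24.8 and Ccn3 (0.92) at 11.7 against 8.39 to 8.66. In knockout 1, Hba-a1 (0.883) stood at 981 CPM against 195 to 288, Ms4a8a (0.892) at 12.4 against 6.19 to 6.86, Pglyrp1 (0.871) at 1200 against 845 to 890 and Mapk7 (0.869) at 45.1 against 41.2 to 41.7. In knockout 4, Tnfaip3 (0.902) stood at 189 CPM against 173 to 174.

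Of 49 genes tested for a difference between the fractions in their knockout change (the CCM genes, the largest changes and the interaction genes, not all list members), 28 differed by the interaction test in edgeR. Many of the 49 were chosen for a small p in that test or for an extreme change in 1 fraction, so their number was partly fixed by the choice and is not a rate. Values are log2 differences, endothelial minus astrocyte. Genes with the higher change in endothelial cells were Ms4a8a (6.57), Serpina1d (5.52), Gpnmb (4.09), AA467197 (3.89), Prr5 (3.47), Chst1 (3.36), Ctnnd2 (3.21), Arl4d (2.91), Nrros (2.70), Tsc22d3 (2.39), Mfsd2a (1.97), Tmcc1 (1.23) and Fzd2 (1.21), with the highest adjusted p for Gpnmb (0.0466). Genes with the lower change in endothelial cells were Syt15 (-5.71), Col14a1 (-4.92), Ndufa4l2 (-4.68), Gpr21 (-4.33), App (-4.0), S1pr3 (-3.82), Pde3a (-3.79), Ccn3 (-3.77), Lox (-3.69), Tll1 (-3.41), Susd4 (-3.35), Gkn3 (-3.21), Vwf (-2.23), Slc4a3 (-2.04) and Map3k20 (-1.71), with the highest adjusted p for Vwf (0.0136). Ms4a8a, Serpina1d and Gkn3 were too low in astrocyte RNA to be tested there alone.

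App rose by 3.49 ± 0.11 in astrocyte RNA of the knockout. Neuronal RNA would raise neuron markers at least as much, but the highest change among 11 of them was 1.53, for Nefm. Endothelial RNA, at the highest marker share of 1.54%, would carry 23.2 CPM of the library total for App, against 2150 CPM added on that scale. The highest change among the 4 nearest tested genes on each side of App was 1.29, for Adamts1, which argues against a change of the whole neighbourhood. A response of astrocytes to the endothelial deletion, and deletion of Pdcd10 within astrocytes, may both underlie the rise, and neither was tested for App.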

How the results depend on the processing

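Leaving out Astro_Flox_3 and Astro_KO_4 together, the other subset fit and the Y-linked covariate were tests chosen only after the results were seen. The endothelial count of 3576 genes was 5611 with limma-voom, 1316 at an adjusted p of 0.01, 1565 at 2-fold or more and 770 with glmTreat. Leaving out 1 library gave 1586 (without control 4) to 3304, with 2110 without knockout 3. The astrocyte count of 3801 was 1294 at an adjusted p of 0.01, 1163 at 2-fold or more and 439 with glmTreat, 2027 without control 3 and knockout 4 together, of which 1841 were shared, and 1556 (without control 2) to 3837 with 1 library left out, including 1975 without control 3 and 2524 without knockout 3. The interaction count of 3255 was 1315, 1886 and 985 under the first 3 of these thresholds, 510 with a replicate block, and 2085 (without astrocyte control 2) to 3291 with 1 library left out. The cell fraction count of 16284 was 15796 to 16381. The 614 genes shared in direction were 113 at an adjusted p of 0.01 and 1459 at an unadjusted p of 0.05. Stricter thresholds call fewer genes by construction, and for the other settings the cause was not tested.

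Of 36 lists, 17 passed camera in endothelial cells, 0 with an estimated correlation, 14 with directional fry (12 of them shared) and 29 with mixed fry, and 14 to 18 with 1 library left out. In astrocyte RNA 27 passed, 0 with an estimated correlation, 16 with directional fry (all shared) and 32 with mixed fry (26 shared), and 22 to 29 with 1 library left out. The camera calls therefore rest on the preset correlation. With the Y-linked covariate, 3090 endothelial and 3803 astrocyte genes were called.

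Among all genes the rule takes, with or without a value in the text, 2213 of 2578 endothelial, 2302 of 2584 astrocyte, 844 of 870 cell fraction and 220 of 220 interaction values kept their direction and their side of the threshold. Calls were lost in 320 endothelial and 270 astrocyte values. Genes that the rule takes, that have no value in the text for the comparison and whose calls were lost when some 1 library was left out included Anpep, Aplnr, Camp, Cd109, Cp, Emp1, Fbln5, Gfap, Ifit2, Il6, Kl, Lgals3, Ly6g, Lyve1, Mvd, Mvk, Ngp, Nqo1, Nr2f2, Osmr, Pdgfrb, Rbfox3, Rsad2, Snap25, Sox9, Spp1, Stmn3, Syt1, Timp1, Tm7sf2 and Ttr in endothelial cells, and Abcc9, Acta2, C1qb, C1s1, Cldn5, Esam, Fkbp5, Ighm, Igkc, Iigp1, Jag1, Kcnj8, Mag, Map3k3, Mcm6, Pcna, Slc40a1, Slc6a13, Slc7a1, Sox10, Steap4, Tmem212, Trem2 and Unc5b in astrocyte RNA. Signs reversed only for genes that did not pass the test: Ccm2 in astrocyte RNA without knockout 2 (-0.0169, up to 0.104 without knockout 3), and in the cell fraction comparison Col1a1 with limma-voom (0.122), with library totals (0.0152) and without endothelial control 2 (0.182), endothelial control 3 (0.264), astrocyte control 2 (0.0684) or astrocyte control 3 (0.0291; lowest -0.854 without endothelial control 4), and Col1a2 without endothelial control 3 (0.0483) or astrocyte control 2 (0.0634; lowest -0.314 without astrocyte control 1). The cause was not tested. Libraries with the same number were not treated as pairs, and with the number as a block 3477 endothelial genes (2669 shared) and 3259 astrocyte genes were called. Deviations from the group means correlated across genes at 0.0677 to 0.356 for same-numbered and -0.326 to 0.174 for other endothelial pairs, and at -0.0998 to -0.0944 and -0.162 to 0.122 for astrocyte pairs.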

Other observations

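Apart from the counts over other splits of the libraries, the tests in this part, and both lists in the next paragraph, were chosen only after the result was seen.

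Of 20 genes induced by glucocorticoids, 13 fell, 0 rose and 7 did not pass the test in astrocyte RNA of the knockout. Tsc22d3 (-2.42 ± 0.16), Zbtb16 (-2.43 ± 0.26) and Hif3a (-2.66 ± 0.24) were among those that fell, and Cdkn1a had 0.96 ± 0.43 without passing. In endothelial cells 6 of the 20 fell. Of 16 circadian clock genes, 7 fell in astrocyte RNA and 1 in endothelial cells. The lists were built after these libraries were seen and hold the genes that prompted them, so these counts were partly fixed by the choice and are not independent evidence. Neither the time of day nor the handling of the animals was analysed here.

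Among genes near Slco1c1, whose promoter drives the recombinase, looked at after their values were seen, Pde3a had a change of 3.77 ± 0.16 in astrocyte RNA (from 1.88 ± 0.3 to 25.4 ± 2.94 CPM), Slco1c1 0.78 ± 0.17 and Slco1a4 1.84 ± 0.41 (adjusted p = 0.0601 without astrocyte control 1, 0.0688 without astrocyte control 2 and 0.0767 without astrocyte control 3, log2 change 1.22 without knockout 4), and Gm6614 had a change of 5.81 ± 0.74 in endothelial cells (from 2.03 ± 2.27 to 119 ± 25.2 CPM). The other 2 of 5 neighbourhood genes tested in astrocyte RNA and the other 7 of 8 tested in endothelial cells did not pass the test, among them Pde3a (0.03 ± 0.19), Slco1c1 (-0.31 ± 0.20) and Slco1a4 (-0.24 ± 0.13) in endothelial cells.

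Pdcd10 was lower in astrocyte RNA, although the deletion was driven from an endothelial promoter. Endothelial RNA, at its highest share of 0.8%, would carry 0.167 CPM of the library total for Pdcd10, against 13.4 CPM lost on that scale. A general fall of astrocyte RNA is argued against by the 17 astrocyte markers, whose median change was -0.35 (SD 0.359) against -1.5 ± 0.16 for Pdcd10. Deletion within astrocytes may be a candidate explanation, since Slco1c1 stood at 240 CPM of the library total in control astrocyte libraries. Counts per gene cannot show the deleted exons, so deletion and lower expression cannot be told apart.

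Of 13 marker lists of other cells, 10 had a median log2 change above 0 in astrocyte RNA of the knockout, highest for erythroid (3.33), endothelial (1.64) and smooth muscle markers (1.39), while fibroblast (-0.01), perivascular macrophage and monocyte (-0.10) and ependymal and choroid plexus markers (-0.58) lay below 0. A lower astrocyte share alone would raise markers of all other cells alike, if astrocytes held none of their RNA. Erythroid markers lay 2.49 above neuron and oligodendrocyte markers in median log2 change. Endothelial markers lay 1.26 above oligodendrocyte markers, a pair picked for its gap. A change in the amount or expression of the cells whose markers rose may remain, besides a lower share, and no biological explanation was tested.

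Other splits of the libraries were counted for each result. In endothelial cells 1 of 35 splits, the real one, gave 3576 genes and the highest other gave 3. A share of 1 in 35 is the smallest these splits can give, so chance was unlikely for that count but not excluded. This holds only if the libraries are separate animals, which the labels do not say. As many lists as the real 17 came from 16 of the 35 splits, with 23 as the highest other, so chance was not excluded for the number of endothelial lists called. For the interaction, 1 of 100 splits, the real one, gave 3255 genes and the highest other gave 488. Genotype was shuffled within each fraction, which removes the genotype effect itself as well as its difference between the fractions. These splits bear on whether genotype had any effect, and cannot decide whether its difference between the fractions arose by chance. The 10 splits of the astrocyte libraries are too few for a share under 0.05: the real split gave 3801 genes (reached by 1 of the 10, itself), with 0 as the highest other, and 27 lists (reached by 2 of the 10), with 28 as the highest other. The same holds for the cell fraction, with 16284 genes from 1 split and 0 as the highest other.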
